A study of Homo sapiens with 8 samples.

How the data were processed

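Total RNA of 8 samples of MDA-MB-231 derivatives, labelled with Cy3, was measured on 1-colour Agilent arrays with 60-mer probes and 62976 spots each. Per the file headers, the scanner images were read with Agilent Feature Extraction, version 10.7.3.1 per the submitters' processing notes, and probe positions are given in hg19. The deposited scanner files give each spot's processed signal as an intensity on a linear scale, background-subtracted by that software, together with its mean signal, local background median and flags. That software also detrended the signal across the array and replaced values at background by surrogates, so small differences between dim spots carry little information. The deposited series matrix holds linear, uncentred intensity values with column medians of 12.5 to 16.1 over all spots. They were identical to the processed signals on all 8 arrays (largest difference 0), so no separate normalization by the authors enters the values. The number of arrays limits the precision.

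The main values were log2 of the processed signal minus each array's 75th percentile over the non-control spots. Control spots and spots flagged as outliers (301 to 432 per array) were left out, and spots of 1 probe were averaged. A probe was tested when it was well above background on at least 3 of the 4 arrays of at least 1 group. This left 24169 of 50599 probes, and the probe with the highest mean was taken for each of 17994 gene names. Gene names of the array design were updated through the RefSeq table of GRCh38.p14, used for names only: 13492 were matched by accession, 661 by symbol or synonym, and 3841 kept the name in the files. Of 135 genes past the test with several tested probes, all other probes had the same sign for 119, and for 0 did another probe pass in the opposite direction.

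Groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in a model with the group only, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The titles number the arrays 1 to 8 with no number shared between groups, so no pairing was fitted. Slide was tested as a batch: 0 genes differed between slides at an adjusted p of 0.05 with group in the model, 564 genes differed between groups with slide as a block, and values were also computed within each slide. Where a probe was not well above background on any array of a group, the fold is a bound: the bright group's mean of normalized log2 values against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

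Before the data were examined, 43 gene lists and the alternatives were fixed, except where the text says that a test was chosen later. Lists were tested with camera (preset correlation 0.01, 2-sided, Benjamini-Hochberg over 43 lists), with camera and an estimated correlation, and with fry, which tests whether a list's genes move, on balance, 1 way. Some genes belong to several lists. A list score per array is the mean of its members' log2 values, each centred over the 8 arrays. The rule for named genes was also fixed before the data were examined: CD274; then the 10 largest increases and 10 largest decreases among genes past the test with fully separated groups, a probe well above background on all 8 arrays and a gene symbol; then up to 5 each way whose probe was not well above background on any array of the other group, as bounds; and from each list described up to 4 members past the test with the smallest adjusted p, or, where none passed, the 2 brightest. Of the listed genes, LYZ, AKR1C2, TRAC, TRBC1 and HIST2H2AA3 had no probe under these names and were not analysed here.

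Alternatives were normexp background correction (offset 50) of the mean and local background signals, quantile and median scaling, no filter, a filter on all 8 arrays, outlier spots kept, the mean of a gene's probes, every probe, an intensity trend with robust eBayes, array weights, slide as a block, the series matrix, a threshold of 0.01, and leaving out each array in turn. Leaving out EMPTY 1 and PDL1 5 together, and leaving out the genes in shifted chromosome windows, were chosen after seeing the data, as were the windows themselves as a test of stretches. Chance was examined by refitting all 35 splits of the 8 arrays into 4 and 4, with the filter recomputed. Chromosome windows were set on 51 neighbouring tested genes (a gene and 25 on either side) against 100 shuffled gene orders. The fit was tested on simulated data for this comparison (17989 genes with the measured means and spreads, 200 of them changed): it called 97.0% of genes changed by 2 on the log2 scale, 76.1% of those changed by 1 and 29.9% of those changed by 0.5, with 8 unchanged genes among 146 calls. A list of 30 other genes was shifted by 0.3, and calls among them count in the 146 but neither as changed nor as unchanged genes. This list passed camera and 0 of 42 unshifted lists did, in data simulated without correlation between genes. Tables were read with data.table, version 1.17.8,, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.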

Results

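The series asked which genes differ in human breast cancer cells according to whether PD-L1 was put back into them. PD-L1, encoded by CD274, is a surface ligand that restrains T cells through the receptor PD-1. The cells were MDA-MB-231, an established line from a breast carcinoma that had spread to the pleural fluid, in which CD274 had been knocked out. They had been transfected with an empty plasmid (group EMPTY, 4 arrays numbered 1 to 4) or with a plasmid expressing PD-L1 cDNA (group PDL1, 4 arrays numbered 5 to 8). Each RNA was hybridized alone, in 1 colour, to an Agilent 60-mer array with 50599 non-control probes. Between 49.19% and 54.32% of the non-control spots of an array were well above background, and 0 were saturated. The 75th percentile of the signal ran from 378.5 to 527.2 intensity units. Each of 2 slides held 2 arrays of each group. The labels describe 1 EMPTY line and 1 PDL1 line and do not say that arrays of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and any other difference between the 2 lines enters every comparison together with PD-L1.

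Log2 signals correlated across genes at r of 0.9908 to 0.9955 within groups and 0.9855 to 0.9919 between them. The first principal component held 34.6% of the variance and separated the groups, with EMPTY arrays at -31.95 to -11.98 and PDL1 arrays at 13.91 to 28.3. The second held 20.5% and set EMPTY 1 (29.9) and PDL1 5 (27.26) apart from the other 6 arrays (-18.54 to -0.81).

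CD274 itself was read by a pair of probes. Probe A_33_P3381513 (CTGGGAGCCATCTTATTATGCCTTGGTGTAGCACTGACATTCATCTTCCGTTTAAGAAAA; hg19, chromosome 9, 5465546 to 5465605) gave 2107 to 4106 intensity units on the 4 PDL1 arrays. On the EMPTY arrays it gave 2.82 to 15.9 units, where values at background are surrogates set by the scanner software, and was not well above background on any of them. CD274 was at least 234-fold higher in PDL1 (limma adjusted p = 0.000226; normalized log2 signal 2.76 ± 0.38 in PDL1 and -6.31 ± 1.19 in EMPTY, SD, n = 4 each). Within slides the same bound on the log2 scale was 7.53 on slide 1 and 8.21 on slide 2, against 7.87 over both. Probe A_23_P338479 (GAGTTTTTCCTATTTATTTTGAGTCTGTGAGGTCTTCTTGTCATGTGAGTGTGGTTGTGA; hg19, chromosome 9, 5468310 to 5468369) lies nearer the 3′ end of the gene and gave only 13.4 to 43.6 units over all 8 arrays. Its log2 difference of 0.36 ± 0.35 (SE, n = 4 per group) did not pass the test (adjusted p = 0.929 over all probes). It was 0.96 on slide 1 and -0.25 on slide 2. The files do not say in which exon or UTR either probe lies, and the labels do not say whether the plasmid or the knocked-out part covers either probe, so a probe outside them checks nothing. The array by array levels of the first probe go with the labels of all 8 arrays, so this probe does check them. The doubt therefore remains for the second probe only.

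**Figure D1:**
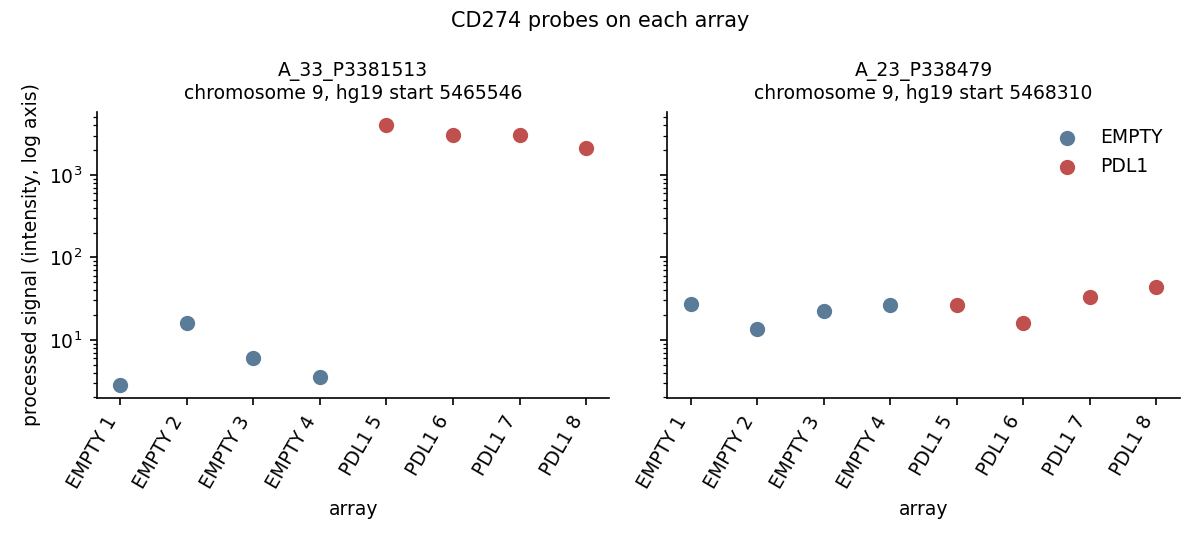
Processed signal (intensity, log axis) of the 2 CD274 probes on each of the 8 arrays; each point is 1 array, blue for EMPTY and red for PDL1. Probe A_33_P3381513 lies between 2107 and 4106 on the PDL1 arrays and at or below 15.9 on the EMPTY arrays, whereas probe A_23_P338479 lies between 13.4 and 43.6 in both groups.

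With CD274 counted, 545 of 17994 tested genes differed between PDL1 and EMPTY (limma, Benjamini-Hochberg adjusted p below 0.05). Of these, 284 were higher and 261 lower in PDL1. The fitted difference was at least 2-fold for 147 genes, 94 higher and 53 lower, of which 89 were well above background on all 8 arrays. With the dimmer group raised to the lowest signal well above background, a limit applied after seeing the data, 124 of the 147 stayed at least 2-fold, 81 higher and 43 lower. With normexp background correction the count was 44. All 4 PDL1 values lay on the same side of all 4 EMPTY values for 545 of the 545, which passing the test on these same values makes likely. Such separation held for 11.88% of the tested genes, against 2.86% by chance. With slide as a block, 564 genes passed, and within slides of 2 against 2 arrays 6 genes passed on slide 1 and 2 on slide 2. The count changed when single arrays were left out, which also leaves fewer arrays to test with. It fell to 195 without EMPTY 2, 165 without EMPTY 3, 221 without EMPTY 4, 281 without PDL1 6, 152 without PDL1 7 and 188 without PDL1 8. The count was 539 without PDL1 5 and 706 without EMPTY 1. Without EMPTY 1 and PDL1 5, the arrays set apart by the second component, 740 genes passed, an alternative chosen after seeing the data.

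The genes with the largest increase among those measured on every array included secreted and surface proteins. DMKN, which encodes the secreted epidermal protein dermokine, was 7.03-fold higher in PDL1 (log2 difference 2.81 ± 0.21, SE, n = 4 per group, adjusted p = 0.000872). IL24, a cytokine of the interleukin-10 family, was 5.82-fold higher (2.54 ± 0.38, adjusted p = 0.0137), and GFRA1, the co-receptor for the growth factor GDNF, 4.96-fold higher (2.31 ± 0.18, adjusted p = 0.00126). PLPP4, a lipid phosphate phosphatase, rose by a log2 difference of 2.17 ± 0.14, and the long non-coding RNA UCA1 by 1.95 ± 0.26. RETREG1, a receptor for autophagy of the endoplasmic reticulum, was 3.64-fold higher. The matrix protease gene MMP3 was 3.59-fold higher (adjusted p = 0.0338), the proteoglycan gene VCAN 3.03-fold (adjusted p = 0.0452) and the secreted metalloprotease gene ADAMTS6 3.02-fold. PTGFR, the prostaglandin F receptor, was 3.22-fold higher. VCAN did not pass with slide as a block (adjusted p = 0.0573) or quantile scaling, nor ADAMTS6 with the mean of its probes. When each of the 8 arrays was left out in turn, MMP3 lost its call in 5 fits and VCAN in 7, and the other 8 genes in 0. IL24 and GFRA1 were dim in EMPTY (normalized log2 signals of -3.78 and -3.95). Over all alternatives the smallest log2 difference was 1.44 for IL24, 1.18 for GFRA1, 1.07 for MMP3 and 1.00 for PTGFR, but 2.08 for DMKN.

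The largest decrease was that of S100A4, a calcium-binding protein linked to cell motility. It lay at a normalized log2 signal of 3.77 ± 0.33 in EMPTY and 1.25 ± 0.56 in PDL1 (SD, n = 4 each), 5.74-fold lower (adjusted p = 0.00437). The acute-phase genes SAA2 and SAA1 were 3.24-fold and 3.20-fold lower, and AKR1C1, an aldo-keto reductase of steroid metabolism, 3.50-fold lower (adjusted p = 0.0361). ADAMTS4, a protease that cleaves aggrecan, was 3.44-fold lower, the cancer antigen gene CAGE1 3.09-fold lower and the glutamate transporter gene SLC1A3 2.79-fold lower. SLCO4A1-AS1, an antisense RNA, was 2.72-fold lower, C1QL1 2.69-fold lower and the interferon-induced membrane protein gene IFITM1 2.50-fold lower (adjusted p = 0.0335). Leaving out single arrays ended the call of AKR1C1 in 6 of 8 fits, of SLCO4A1-AS1 and IFITM1 in 5 each and of C1QL1 in 4, and of the other 6 in 0. ADAMTS4 and C1QL1 were dim in PDL1 (normalized log2 signals of -3.97 and -3.36). Over all alternatives the smallest decrease on the log2 scale was -0.86 for ADAMTS4, -0.88 for SLC1A3 and -0.76 for C1QL1, but -2.33 for S100A4. Near-identical copies can share probes, so the gene is uncertain for SAA1, SAA2 and AKR1C1, and likewise for XAGE2 and the HLA genes below.

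**Figure D2:**
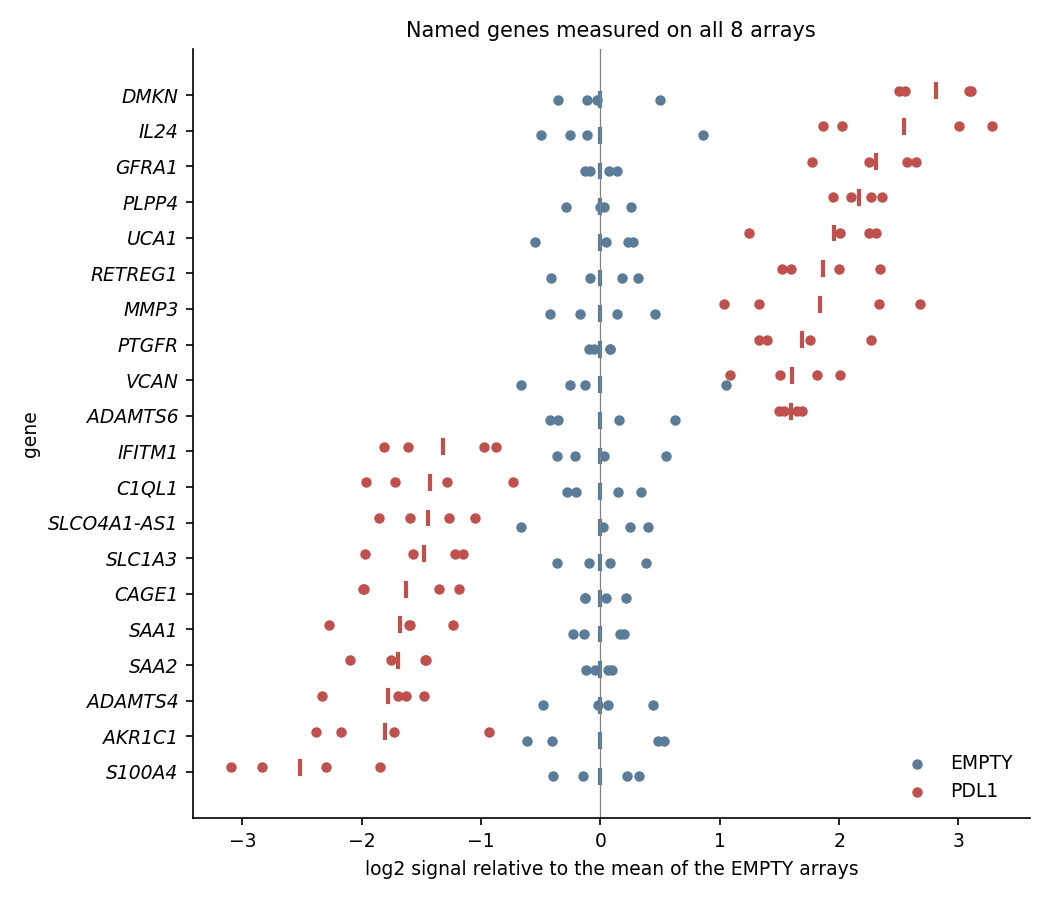
Normalized log2 signal on each array, relative to the mean of the 4 EMPTY arrays, for the 10 genes with the largest increase and the 10 with the largest decrease among those well above background on all 8 arrays; points are arrays (blue EMPTY, red PDL1) and short bars group means. For every gene shown the 4 PDL1 arrays lie on 1 side of the 4 EMPTY arrays, as the rule for naming genes required. The group means differ by 2.81 for DMKN to -2.52 for S100A4.

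Other genes were well above background in only 1 of the groups, and their differences are bounds against the lowest signal that counted as well above background. RASEF, a GTPase of the Rab family, was at least 4.73-fold higher in PDL1 (adjusted p = 0.00349). PGCKA1 was at least 3.09-fold higher, the trypsin inhibitor gene SPINK1 at least 2.38-fold, the cancer-testis antigen gene XAGE2 at least 2.25-fold and the bicarbonate transporter gene SLC4A4 at least 1.61-fold. In the other direction, KLHDC9 was at least 2.40-fold lower, the protease gene ADAMTS9 at least 2.35-fold, OAS1, an interferon-induced sensor of double-stranded RNA, at least 1.49-fold, FAM133A at least 1.43-fold and the adenosine receptor gene ADORA2A at least 1.21-fold. With normexp background correction only RASEF, PGCKA1 and ADAMTS9 of these 10 passed. OAS1 also did not pass with slide as a block (adjusted p = 0.052) or quantile scaling. In fits without 1 array SPINK1 lost its call in 4, OAS1 in 3 and FAM133A in 2, and the other 7 in 0; these 3 genes, SLC4A4 and KLHDC9 were too dim to be tested in 3 of the 8 fits. Of the 30 genes named by size, 28 passed with slide as a block.

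Of 22 measured genes of MHC class I antigen presentation, 18 had a negative difference, with a median of -0.34 (-0.39 on slide 1, -0.26 on slide 2; camera adjusted p = 2.6e-05, and 2.03e-06 with slide as a block). The list did not pass when the correlation among members was estimated (adjusted p = 0.776 with an estimated correlation) or with fry (adjusted p = 0.115). Of these members, 2 fell past the test over all genes, the immunoproteasome subunit gene PSMB9 (1.43-fold lower, adjusted p = 0.0376) and the peptide-trimming protease gene ERAP2 (1.45-fold lower, adjusted p = 0.0437). Adjusted over the list alone, 12 were lower and 1 higher. Its 6 HLA class I genes, with a median of -0.50, lay in a stretch of chromosome 6 where neighbouring genes were lower as well, and the other 16 had a median of -0.19. The interferon response list had a median of -0.31 over 36 members (camera adjusted p = 0.000758, and adjusted p = 0.776 with an estimated correlation; -0.45 on slide 1 and -0.04 on slide 2). IFITM1, OAS1 and LGALS3BP fell, LGALS3BP by 1.35-fold, and 33 members did not pass. Adjusted over the list alone, 5 were lower and 0 higher. On EMPTY 1 the interferon score was -0.19, within the range of the PDL1 arrays (-0.32 to 0.13). Among interferon gamma and IRF1 targets HLA-DMA alone of 16 members passed, 1.79-fold lower, and the list did not (camera adjusted p = 0.0626; 4 lower and 0 higher adjusted over the list alone). Of the nucleic acid sensing genes DHX58 fell 1.64-fold, but did not pass with slide as a block (adjusted p = 0.0507), and of 20 checkpoint and costimulatory ligands other than CD274 only NT5E, which makes adenosine, passed, 1.65-fold lower; the list tests gave camera adjusted p = 0.392 and 0.0866. Adjusted over the list alone, 3 sensing genes were lower and 2 higher, and 1 ligand was lower and 1 higher. For NF-kB and inflammatory genes 2 members passed lower (SAA1, SAA2) and 1 higher (IL24) out of 29 (camera adjusted p = 0.503; 5 lower and 3 higher adjusted over the list alone). ERAP2 and LGALS3BP did not pass with normexp or median scaling, DHX58 with median scaling or NT5E with the mean of its probes. Of the 8 fits without 1 array, ERAP2 and LGALS3BP lost their calls in 7, PSMB9 and DHX58 in 6, and HLA-DMA and NT5E in 5.

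The fatty acid synthesis list had a median of -0.30 over 16 members (camera adjusted p = 0.00342, and adjusted p = 0.776 with an estimated correlation; -0.43 on slide 1 and -0.10 on slide 2). Its rate-limiting enzyme gene ACACA was 1.56-fold lower (adjusted p = 0.0175) and FASN 1.34-fold lower (adjusted p = 0.0437, but 0.0567 with slide as a block); the other 14 did not pass, and adjusted over the list alone 5 were lower and 2 higher. In the cholesterol list 22 of 25 members had negative differences (median -0.26; camera adjusted p = 0.00733, and adjusted p = 0.836 with an estimated correlation), but 0 passed singly or adjusted over the list alone, and the median was -0.50 on slide 1 and 0.06 on slide 2. Its brightest members, FDPS and ACAT2, differed by -0.20 ± 0.14 and -0.07 ± 0.16 (SE, n = 4 per group). Of 24 NRF2 targets, 4 fell (median of the list -0.20, -0.12 on slide 1 and -0.19 on slide 2; camera adjusted p = 0.00342, and adjusted p = 0.776 with an estimated correlation; 6 lower and 0 higher adjusted over the list alone). These were the reductases AKR1C1 and AKR1B10 (1.74-fold lower), the transporter gene ABCC2 (1.83-fold lower) and TKT of the pentose phosphate pathway (1.31-fold lower). The stress lists had positive medians. The unfolded protein response list had a median of 0.21 over 19 members (0.14 on slide 1, 0.19 on slide 2; camera adjusted p = 0.0164) and the ATF4 and integrated stress response list 0.17 over 30 members (0.14 and 0.17; camera adjusted p = 0.0175). Neither passed with an estimated correlation (adjusted p = 0.776 for each) or with fry (adjusted p = 0.21 and 0.115). In neither did a member pass over all genes; adjusted over the list alone, 1 unfolded protein response gene was higher and 0 ATF4 genes. The brightest members were SDF2L1 (0.40 ± 0.21) and HSP90B1 (0.23 ± 0.14), and ATF4 (0.37 ± 0.14) and SARS1 (-0.11 ± 0.09; SE, n = 4 per group). Single calls ended for FASN, TKT and ABCC2 with median scaling, TKT and ABCC2 with quantile scaling, AKR1B10 with normexp, and ACACA, AKR1C1, AKR1B10 and ABCC2 with the mean of probes. In fits without 1 array the calls of FASN and TKT ended in 7, of AKR1B10 and ABCC2 in 6 and of ACACA in 4. The arrays set apart by the second component overlapped the other group: the score of EMPTY 1 was within the PDL1 range for cholesterol (-0.27; PDL1 -0.34 to 0.28) and fatty acid genes (-0.04; PDL1 -0.27 to -0.01). For cholesterol genes PDL1 6 (0.28) scored above EMPTY 3 (0.16) and EMPTY 4 (0.24). The score of PDL1 5 was within the EMPTY range for NRF2 (0.03; EMPTY 0.02 to 0.26), unfolded protein response (-0.13; EMPTY -0.22 to 0.01) and ATF4 genes (-0.01; EMPTY -0.15 to 0.03). With slide as a block each of these 5 lists passed camera with the preset correlation. Single arrays ended some of these calls: that of the unfolded protein response list without EMPTY 1 (adjusted p = 0.136) or PDL1 6 (0.0704), that of the ATF4 list without PDL1 7 (0.0547) and that of the cholesterol list without EMPTY 2 (0.0989), PDL1 5 (0.0554) or PDL1 8 (0.0881). At least 7 lists passed in 16 of the 35 ways of splitting the 8 arrays into 4 and 4.

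**Figure D3:**
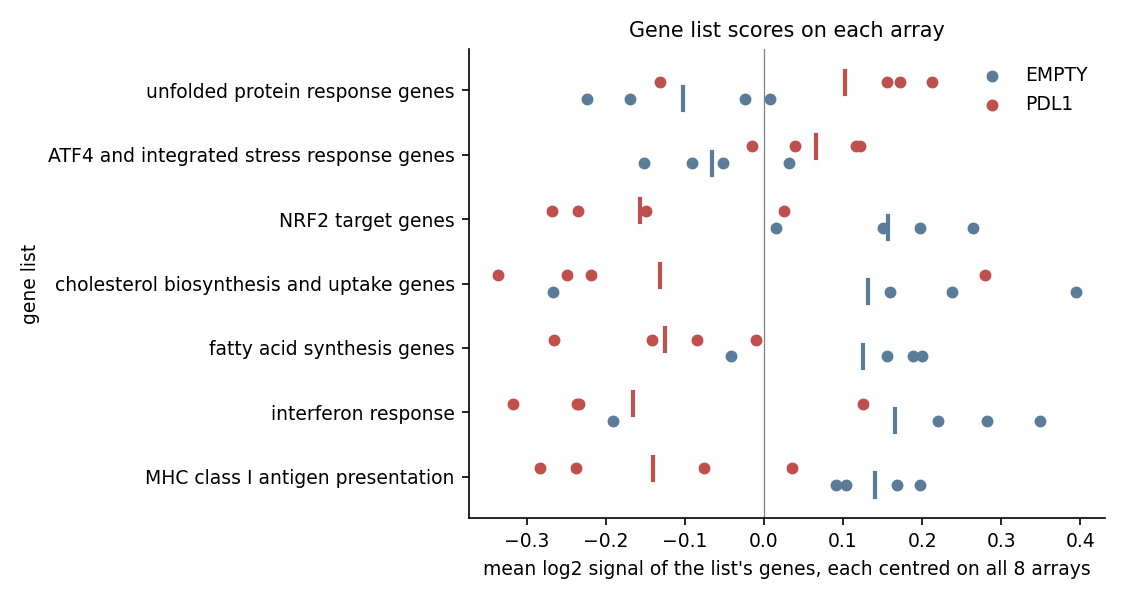
Score of each of the 7 gene lists that passed camera with the preset correlation: the mean over members of the normalized log2 signal, each gene centred on all 8 arrays. Points are arrays (blue EMPTY, red PDL1) and short bars group means; MHC class I is the only 1 of the 7 whose groups do not overlap, with EMPTY at 0.09 to 0.20 and PDL1 at -0.28 to 0.04.

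Lists of cell identity, matrix and signalling did not pass camera, but single members passed the test over all genes. The lists described here passed fry for a change in either direction. Its adjusted p ran from 1.3e-08 for mesenchymal genes to 0.0067 for YAP and TAZ targets. Among TGF-beta targets INHBA (2.01-fold, adjusted p = 0.00405), FSTL3 (1.86-fold) and TGFBI (1.63-fold) rose, and 0 of 20 fell, in the count over all genes and in that adjusted over the list alone (3 higher; camera adjusted p = 0.503). Of 20 mesenchymal genes CDH11 rose 2.22-fold and S100A4 fell (camera adjusted p = 0.971; 3 higher and 2 lower adjusted over the list alone), and of 19 epithelial genes the keratins KRT81 (1.59-fold) and KRT7 (1.52-fold) rose (camera adjusted p = 0.359; 4 higher and 1 lower over the list alone). In the collagen and matrix list MMP3 and SPOCK1 (1.71-fold) rose and COL6A1 (1.71-fold) fell. Among WNT targets NKD1 (at least 1.59-fold, as 2 EMPTY arrays were not well above background, and lost with normexp) and DKK3 (1.46-fold) rose and FZD8 (1.95-fold) and WNT5A (1.85-fold) fell. Among growth factor receptors and ligands EFNB1 (1.53-fold) rose and EPHB4 (1.61-fold) and TGFBR3 (1.57-fold) fell, and of the adhesion receptors NRCAM (1.79-fold) and L1CAM (1.81-fold) fell, L1CAM without passing when slide was a block (adjusted p = 0.0546). AREG, an EGF receptor ligand in the ERK output list, rose 2.50-fold (adjusted p = 0.0235). The heat shock gene HSPB8 rose 2.01-fold and ID2, in the stemness list, 1.95-fold. NT5E fell among YAP and TAZ targets as well. Of the genes in these lists, NKD1, DKK3, TGFBR3 and NRCAM did not pass with normexp, DKK3, COL6A1, EFNB1 and L1CAM with median scaling, NKD1 and COL6A1 with quantile scaling, DKK3, COL6A1 and NT5E with the mean of probes, or DKK3 with trend and robust settings. INHBA, FSTL3, TGFBI, CDH11, KRT81, SPOCK1, EPHB4 and ID2 passed whenever a single array was left out. The calls of WNT5A, TGFBR3 and L1CAM ended in 7 of these 8 fits, of COL6A1, DKK3 and FZD8 in 6, of KRT7 in 5, of NKD1 and AREG in 4, of EFNB1 and NRCAM in 3 and of HSPB8 in 2. The camera adjusted p was 0.999 for matrix, 0.828 for WNT, 0.392 for growth factor receptors, 0.828 for adhesion, 0.359 for ERK output, 0.381 for heat shock, 0.392 for stemness and 0.487 for YAP and TAZ genes. Adjusted over the list alone, the counts higher and lower were 3 and 2 for matrix, 4 and 5 for WNT, 5 and 4 for growth factor receptors, 5 and 5 for adhesion, 1 and 3 for ERK output, 2 and 0 for heat shock, 3 and 2 for stemness, and 3 and 1 for YAP and TAZ genes.

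Many of the lower genes were neighbours on a chromosome. In windows of 51 neighbouring tested genes (hg19 order), medians beyond those of shuffled gene orders formed 8 stretches lower and 3 higher in PDL1, a test chosen after seeing the data. The lower stretches held 124 of the 261 lower genes and 6 higher genes, and the higher stretches held 16 of the 284 higher genes and 1 lower gene. All stretches together held 2331 of the 17994 tested genes. They were picked by these same differences, so some excess of genes with the sign of the stretch is built in. FASN, ACACA, LGALS3BP, DHX58, C1QL1 and PECAM1 lay in the lower stretches of chromosome 17, TKT, WNT5A and ADAMTS9 in that of chromosome 3, NT5E and SESN1 in the stretch of chromosome 6 from 74210376 to 138203738, apart from that of the HLA genes, EPHB4 in that of chromosome 7 and TGFBR3 in that of chromosome 1. XAGE2 lay in a higher stretch of chromosome X. SARS1, which did not pass the test, also lay in a shifted window.

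**Figure D4:**
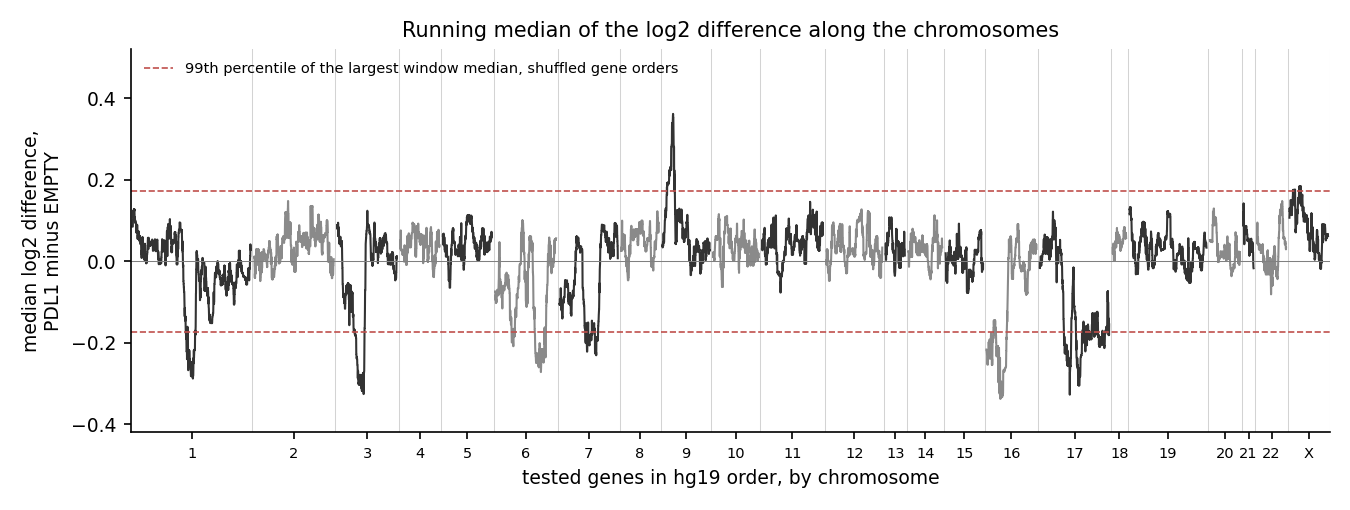
Running median of the log2 difference (PDL1 minus EMPTY) over neighbouring tested genes, in hg19 order by chromosome; dashed lines mark 0.17 above and below 0, the 99th percentile of the largest window median in 100 shuffled gene orders. The track passes below the lower line on chromosomes 1, 3, 6, 7, 16 and 17 and above the upper line on chromosomes 9 and X.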

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

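The test of slide for the arrays EMPTY 1 and PDL1 5 was chosen only after the result was seen. Each of 234 groups of 4 arrays (named genes past the test, CD274 probes, list scores and measures of array quality, in EMPTY and in PDL1) was tested for an array far from the other 3, by the gap to its neighbour over the whole range (Dixon's test at the 95% level). Of these groups 11 were past its critical value. Chance alone gives about 1 in 20, which is about as many, so no single case below shows that an array is unusual.

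Among genes, PSMB9 lay at a normalized log2 signal of 3.73 on EMPTY 1 against 3.44 to 3.48 on the other EMPTY arrays (gap over range 0.856). CSF1R lay at -1.24 on EMPTY 1 against -0.88 to -0.82 (0.856). COL6A1 lay at 4.60 on PDL1 5 against 4.24 to 4.30 on the other PDL1 arrays (0.835), and FASN at 3.82 on PDL1 6 against 3.56 to 3.59 (0.887).

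Among list scores, EMPTY 1 was low for checkpoint ligands (-0.05 against 0.10; gap over range 0.956), for WNT genes (-0.21 against 0.09 to 0.11; 0.949) and for basal breast genes (-0.31 against 0.14 to 0.18; 0.906). PDL1 5 was high for G2/M genes (0.17 against -0.12 to -0.08; 0.874) and low for unfolded protein response genes (-0.13 against 0.16 to 0.21; 0.835). PDL1 6 was low for MYC and ribosome biogenesis genes (-0.13 against 0.08 to 0.10; 0.890), and PDL1 8 was high for housekeeping genes (0.06 against 0.01; 0.884).

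Of these 11, EMPTY 1 or PDL1 5 was the distant array in 8, and the second principal component set the same arrays apart from the other 6, with deviations from their group means that correlated across genes at 0.338 (genes are not independent replicates). Both lay on slide 2, but a shift shared by that slide's arrays would move PDL1 6 with them, whereas it lay at the other end of the component (-18.54) and its deviations correlated with those of EMPTY 1 at -0.304, a restatement of the pattern already seen. Probe GC content (Spearman -0.0832 with the component's loadings across genes) and signal level (0.0912) were both under the bound of 0.1 set in advance. No biological explanation was tested, since the labels give no feature that these arrays share. What set them apart stays open.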

How the results depend on the processing

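Leaving out EMPTY 1 and PDL1 5 together, and leaving out genes in shifted chromosome windows, were chosen only after the result was seen. The difference of CD274, a bound of 7.87 on the log2 scale, kept its direction and passed the test in every alternative that gave a value. It was 5.57 with normexp and 7.71 to 8.10 when single arrays were left out. With the mean of its probes, which takes in the dim second probe, it was 4.06. The filter on all 8 arrays removes its probe and gave no value. The 545 genes became 18 without a filter, 1175 with array weights (weights of 0.51 for EMPTY 1 and 0.63 for PDL1 5), 68 at an adjusted p below 0.01 and 345 without the genes in shifted windows, and ranged from 152 (without PDL1 7) to 706 (without EMPTY 1). Without a filter, 36337 genes were tested: the number of tests alone left 208 genes, and the larger pooled variance alone left 56. The 147 genes of at least 2-fold became 44 with normexp, 17 without a filter and 232 with array weights, and ranged from 83 to 194 when single arrays were left out, falling most without EMPTY 3 (83), PDL1 7 (85) and PDL1 8 (94). The 7 lists became 0 with an estimated correlation, 0 with fry (30 changed in either direction), 11 without EMPTY 1 and PDL1 5, and 11 without the genes in shifted windows, and ranged from 6 to 12 (without EMPTY 1) when single arrays were left out. Apart from the filter, the threshold and the smaller sets of genes or arrays, the cause was not tested.

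The gene count stayed within 1.5 times 545 under the other alternatives: 485 with normexp, 523 with quantile scaling (478 shared), 385 with median scaling (352 shared), 582 with the filter on all 8 arrays, 546 with outlier spots kept, 501 with the mean of probes, 584 over probes, 794 with trend and robust settings, and 564 with slide as a block (467 shared). The series matrix gave 545, as its values are identical. Scaling was first set down as an explanation to test for the gene count and the MHC class I list, and is given here instead: that list's adjusted p was 5.41e-05 with quantile and 0.00014 with median scaling. Median scaling moved the median of all genes from 0.01 to -0.04 and the share of higher genes from 52.1% to 44.4%. It also moved 5 list medians by more than their spread, turning those of the mesenchymal genes (-0.04) and p53 targets (-0.01). Of 68 named genes past the test, 29 passed in every fit without a single array that tested them. In the other alternatives set in advance, that without a filter aside, 37 passed in each one that tested them. Some genes given as bounds were too dim to be tested in all of these fits. Without a filter 60 did not pass, and 0 reversed in any setting. Signal over background limits the genes given as bounds.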

Other observations

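In the G1/S, G2/M, DNA repair, histone, ribosomal protein, MYC, oxidative phosphorylation, glycolysis, hypoxia, autophagy and lysosome, Notch, luminal, basal and housekeeping lists, 0 members passed limma over all genes. Of these lists, the luminal (0.000436), autophagy (0.0153), hypoxia (0.0228), housekeeping (0.0306) and oxidative phosphorylation (0.0364) lists passed fry for a change in either direction (adjusted p in parentheses). Passing this test was common, as 30 of all lists did. The smallest adjusted p values were those of the mesenchymal (1.3e-08), adhesion (3.4e-06) and NF-kB lists (3.4e-06). The brightest members of the cell cycle lists, TK1 and MCM7, differed by -0.16 ± 0.09 and -0.32 ± 0.12 on the log2 scale, and UBE2C and BIRC5 by 0.04 ± 0.15 and -0.10 ± 0.10 (SE, n = 4 per group). GAPDH differed by -0.03 ± 0.08, LDHB by -0.01 ± 0.14, the hypoxia genes ADM and BNIP3 by -0.25 ± 0.20 and -0.07 ± 0.11, and the basal genes ITGB4 and CAV1 by -0.61 ± 0.15 and -0.22 ± 0.09. Of the genes just named, TK1, MCM7, BIRC5 and ITGB4 lay in shifted chromosome windows, and the others did not. Camera adjusted p values were 0.131 for G1/S and for oxidative phosphorylation genes, 0.392 for G2/M, glycolysis, autophagy, basal, MYC and housekeeping genes, 0.595 for DNA repair, 0.945 for histone, 0.261 for ribosomal protein, 0.088 for hypoxia, 0.875 for Notch and 0.696 for luminal genes. Adjusted over the list alone, 1 member was lower in the glycolysis, autophagy, basal and luminal lists, 1 was higher in the autophagy and luminal lists, and 0 differed in the other 10. Of 26 p53 targets SESN1 fell 1.41-fold (camera adjusted p = 0.696; 1 lower adjusted over the list alone). Of 27 apoptosis regulators BCL2A1, a survival factor of the BCL2 family, rose 1.42-fold and TNFRSF11B, a decoy receptor for TRAIL and RANKL, was at least 1.74-fold lower, with 1 PDL1 array well above background and the call lost with normexp (camera adjusted p = 0.392; 4 higher and 2 lower adjusted over the list alone). SESN1 did not pass with normexp or with trend and robust settings, nor BCL2A1 with median scaling. Leaving out single arrays ended the call of BCL2A1 in 7 fits, of SESN1 in 6 and of TNFRSF11B in 4. The 13 measured neighbours of CD274 on chromosome 9 had 0 members past the test over all genes or the list alone (camera adjusted p = 0.75; AK3 -0.13 ± 0.18, RCL1 0.03 ± 0.11).

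Markers of other cell types moved singly. CD8A was 1.84-fold higher and CD3D 1.42-fold lower, both dim (normalized log2 signals of -4.12 to -2.54), and 5 other lymphocyte markers did not pass (camera adjusted p = 0.779; 1 higher and 1 lower adjusted over the list alone). CD3D did not pass with normexp, median scaling or trend and robust settings, nor CD8A with the mean of its probes. CSF1R was 1.52-fold lower (myeloid markers, camera adjusted p = 0.088; 2 lower over the list alone) and PECAM1, which lay in a lower stretch of chromosome 17, 2.46-fold lower (endothelial markers, 0.945; 1 lower). Leaving out single arrays ended the calls of CD3D and CSF1R in 7 fits, of PECAM1 in 4 and of CD8A in 2. Of 5 fibroblast markers 0 passed (camera adjusted p = 0.406; 1 lower over the list alone), with PDGFRB at -1.32 ± 0.32 and FBLN1 at 0.10 ± 0.19. The sign of the median, mean and test differed for the lymphocyte, adhesion, endothelial, histone, mesenchymal and matrix lists.

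The counts of genes by splits, the tests of state among arrays and the windows as stretches were chosen only after the result was seen. The splits ask only whether a chance division of these 8 arrays would give as much, not whether the 2 lines differ by chance, as each group is 1 line. A chance division is unlikely for the 545 genes but not excluded, as the smallest exact 2-sided p that these splits can give is 0.0286. Of the 35 splits into 4 and 4 only 1, the real one, gave as many, and the highest other gave 50. A chance division is likewise unlikely for the 147 genes of at least 2-fold (1 of 35, highest other 19). For the 7 lists it is not even unlikely, since 16 of the 35 splits gave as many and the highest other gave 16. For the 2331 tested genes in shifted windows 1 of 35 splits gave as many, and the highest other, 2051, came from a split that exchanges only EMPTY 2 and PDL1 8.

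Genes that differed lay together on chromosomes. There were 35 adjacent pairs with the same sign, against a mean of 8.24 and at most 15 in shuffled orders. Names on the array can lie close together, as LRIG2 (113667055) and XLOC_000350 (113674687) do on chromosome 1, both lower. Shuffling parts such names, so part of the excess need not come from longer stretches. The 11 stretches had medians of -0.232 to -0.166 in 8 and 0.15 to 0.194 in 3 (largest within-group SD 0.0607). Each stretch separated the groups, which adds no support, since the stretches were picked by the difference between these same groups. Probe GC content was argued against, since 97.86% of the called genes in windows stayed there after its correction. A difference in copy number between the lines is a candidate explanation for the stretches, since 76.68% of 1278 tested genes left out when windows were set had their window's sign, though any other change along a stretch would give this too. Of all called genes 25.93% lay in windows shifted in their own direction (47.5% of the lower and 5.63% of the higher). Another 7 lay in stretches of the other direction. Without the genes in shifted windows 345 genes still passed (233 higher and 112 lower). These values argue against the stretches as the cause of all called genes. Copy number changes shorter than a window were not looked for, so copy number as a cause outside the stretches stays open. Any other difference between the lines cannot be told apart from PD-L1, since the labels name 1 line per group.

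The lower MHC class I list could follow from probes shared among HLA genes or from the chromosome 6 stretch. Without the 6 HLA genes the camera p was 0.000668, and without members in windows, the same 16 genes against other genes outside windows, 6.75e-05, which met the bounds set in advance against either cause. These bounds were set aside after the values were seen, because 16 of 35 splits gave as many lists with that preset correlation, and with an estimated correlation the p was 0.0868 and 0.0536. Genes past the ends of that chromosome 6 stretch (29430022 to 32009022) counted as outside it, so a shift reaching further was not removed. Both causes therefore stay open, as does a difference of state among arrays: the lowest EMPTY score was above the highest PDL1 score by 0.0549, within 1 within-group SD (0.110). For the interferon list the scores overlapped (-0.317; SD 0.222), as a difference of state among arrays may give.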
